A study of Mus musculus with 9 samples.

How the data were processed

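The study sequenced poly(A) RNA from isolated stomach corpus glands of mice of 3 genotypes, with 3 libraries each, prepared with a stranded mRNA kit per the labels' protocols. The deposited table holds FPKM values (fragments per kilobase of transcript, scaled to the mapped reads) for 18423 genes in 9 libraries. The submitters' notes name STAR 2.4.2a for alignment and the builds GRCm38 and mm10. The sources used here do not say which tool counted reads and made the FPKM values or whether reads with several matches were counted. Gapdh, which has many pseudogenes, held 10 to 95 reads per library, so genes with near-identical copies were treated as uncertain.

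From these values whole reads were worked out, since every FPKM value of a gene is a multiple of the worth of 1 read in that library. All 18423 genes came out whole in every library within a tolerance of 0.01, at 22653249 to 29478481 reads per library, and on simulated data 96.8% of genes gave the exact reads. Reads were used for depth, shares of reads and the alternative with limma voom. Bootstrap intervals resample loci or genes, not libraries.

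Groups were taken from the genotype in the labels. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), on values as deposited, with all 9 libraries in 1 fit of 3 group means, so that the groups share an estimate of the spread. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 11209 in all, and 7214 were left out. The Benjamini-Hochberg adjusted p had to be under 0.05. The 3 comparisons were Ctrl against WT, Arid1a_Het against Ctrl and Arid1a_Het against WT. For Arid1a an exact two-sided permutation test of 3 against 3 libraries was added, which cannot give a p below 0.1. The fit was tested on simulated libraries in which 100 genes were changed by a log2 of 1 and 100 by 2. Noise was independent between genes, so the rates may not carry over to these data. Genes changed by 1 were recovered in 47%, 58% and 52% of cases in the 3 comparisons and those changed by 2 in 92%, 91% and 92%, with 9, 9 and 4 calls among unchanged genes.

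Gene lists, 33 with 673 symbols of which 658 are in the table, cover the cell types of the corpus, tissue that could be carried over, and pathways of the transgenes and of chromatin. Each of the 30 lists with at least 5 tested members, the sex check excluded, was compared with all other genes by camera in limma with its preset correlation of 0.01, adjusted over the lists. With the correlation estimated from the data 0 lists passed in any comparison, so a list call rests on the preset value. Counts of members are given over all genes tested and adjusted over the list alone, and medians relative to the median of all tested genes.

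Genes were named by a rule: Arid1a; in each direction the 10 largest changes among called genes whose groups do not overlap, leaving out unnamed transcripts, small RNAs and pseudogenes, or the 5 of lowest p where none passed; up to 4 members of lowest p of each list; and the highest member of each list for other tissues or sex. The groups, the test, the lists, this rule and most alternatives were fixed before the data were examined. The rule takes 422 gene results, and a part of them, 179 with Mir7688, is named; it was picked when it was known which genes changed sign under an alternative, and leaves those out, all of which had missed the threshold. The other results of the rule are not reported here. Positions are from GENCODE M21 on GRCm38, which holds 18301 of the 18423 symbols.

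Alternatives were a pseudocount of 0.1 or 0.01, no filter, a minimum FPKM of 5, median-ratio scaling, a total without the 50 highest genes, quantile normalization, a fit of only the groups compared, robust or untrended eBayes, array weights, the replicate number as a block, a 2-fold minimum, and each library left out. Libraries of WT and Ctrl with the same number deviated from their group means together, with correlations of 0.207, 0.336 and 0.138. As each exceeds 0.1, the numbers were taken to pair these groups, on the data alone, since the labels do not say so. The block fit holds all 9 libraries. Added after the data were seen were a fit without the libraries with pancreas reads, limma voom on whole reads, a fit without small RNA genes, and a simulation of overlaps that keeps the pairing. For overlaps between comparisons, unchanged groups were simulated from the residuals of the 9 libraries in 1000 draws, of which 996 gave a value, and again with WT and Ctrl libraries of a number drawn together (997 of 1000). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the reads, positions and plots.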

Results

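Poly(A) RNA was sequenced from glands of the acid-secreting stomach corpus, in 9 libraries of 3 genotypes with 3 each. Glands were loosened with EDTA and scraped from tumour-bearing corpus or, in normal stomachs, from the matching place. The first genotype was wild type (WT). The second, Ctrl, carried Cre recombinase under Atp4b, the gene of a proton pump subunit of parietal cells, together with a Rosa26 allele for the Notch intracellular domain (NICD), the active form of the Notch receptor. The third, Arid1a_Het, carried both transgenes and a loxP-flanked copy of Arid1a beside a normal copy. Arid1a encodes a subunit of the BAF (SWI/SNF) chromatin remodelling complex, and the series title names its dosage in gastric tumour formation as the subject. Ctrl against WT asks what differs with the NICD transgene, Arid1a_Het against Ctrl what differs with loss of a copy of Arid1a as well, and Arid1a_Het against WT what differs with both.

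Each library is described as from a mouse of its genotype, but the labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. Arid1a_Het 3 was registered apart from the other libraries, and an effect of separate preparation was not tested. Values below are FPKM, given as mean ± SD with n = 3 libraries per group. Log2 fold changes (log2FC) are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes were called at an adjusted p under 0.05 in limma, and lists were tested by camera. WT and Ctrl libraries of the same number had correlated deviations and were assumed to be pairs, without a test against other matchings. For Ctrl against WT a value with the replicate number as a block is therefore given where it changes a call or moves a count by over 1.5 times. Calls of named genes that were lost are counted over 22 to 24 alternatives per gene. In lists of libraries left out one at a time, Ctrl 1/3 stands for Ctrl 1 or Ctrl 3.

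The first principal component took 54.9% of the variance and the second 17.8%. On the first component WT 2 lay at 68.5, against 28.0 and 37.2 for the other WT libraries and -44.1 for Ctrl 3. Pgc, the pepsinogen C gene of chief cells, took 17.9% of all FPKM in Arid1a_Het 2 and 16.5% in WT 2, but 1.49% in Ctrl 1. Genes of the exocrine pancreas, which lies next to the stomach, held 5169 RPM (reads scaled to library depth) in Ctrl 1 and 2019 in Arid1a_Het 3, against 102 to 373 in the other 7 libraries. Fits without both are given below as those with no pancreas libraries. The highest gene of each list for other tissues ranged widely over the 9 libraries: the elastase Cela1 from 79.4 to 1014 FPKM, the squamous gene Sprr1a from 43.6 to 647 FPKM and the erythroid enzyme Alas2 from 0.261 to 12.0 FPKM. The mast cell protease Mcpt2 ran from 12.0 to 389 FPKM, the matrix gene Dcn from 1.83 to 60.3 FPKM, the smooth muscle gene Smtn from 1.59 to 6.11 FPKM and the endothelial gene Esam from 1.77 to 4.09 FPKM. The Y-linked gene Eif2s3y ran from 8.76 to 14.7 FPKM, and Xist was at most 0.00389 FPKM in any library.

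Reads over microRNA and small nucleolar RNA loci were higher in Ctrl, at 379 ± 87.6 RPM over 441 loci, than in WT, at 150.0 ± 28.7, and in Arid1a_Het, at 135 ± 19.3. Every Ctrl library lay above the 6 others, with an exact two-sided permutation p of 0.1 in each of the 2 comparisons with Ctrl, the smallest that 3 against 3 libraries allow. Of 143 loci tested, 19 were called higher in Ctrl than in WT, and 49 with the replicate block.

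**Figure D1:**
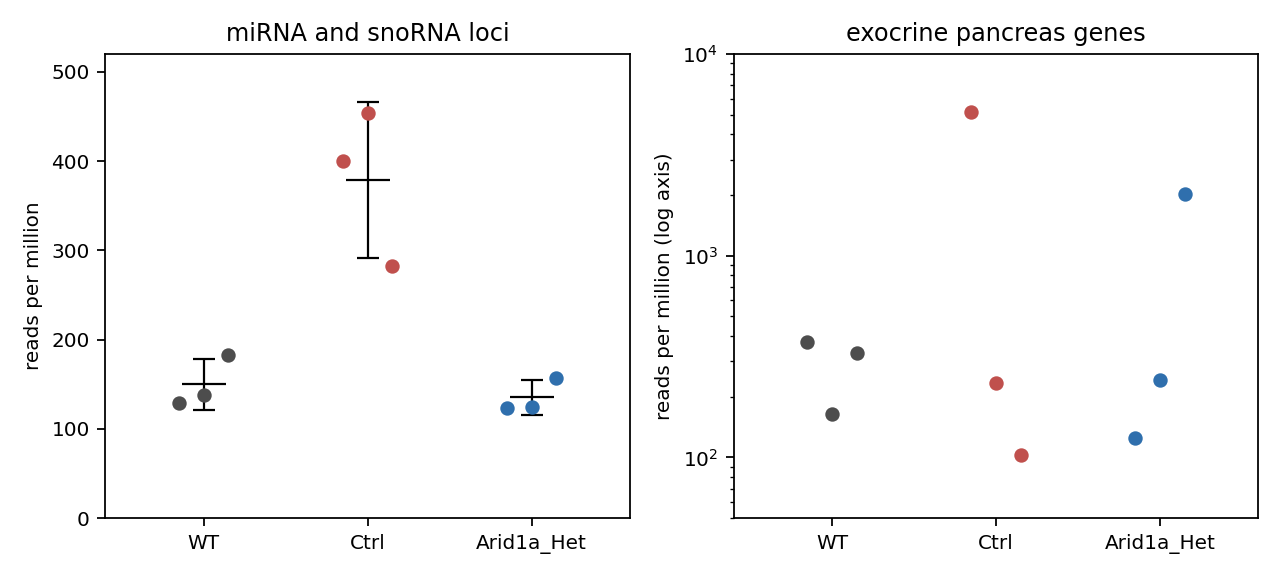
RPM over microRNA and small nucleolar RNA loci (left, linear axis, bars mean ± SD of 3 libraries) and over exocrine pancreas genes (right, log axis), with a point per library in WT, Ctrl and Arid1a_Het. The 3 Ctrl points on the left lie above the 6 others, and Ctrl 1 and Arid1a_Het 3 stand above the other 7 libraries on the right.

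Arid1a, at chromosome 4, 133679008 to 133756769 on the minus strand of GRCm38, was lowest in the libraries that carry the loxP-flanked copy. Its level was 7.26 ± 1.54 FPKM in Arid1a_Het, 14.8 ± 1.44 in Ctrl and 11.1 ± 2.94 in WT. Single libraries held 8.94, 5.90 and 6.96 FPKM in Arid1a_Het, 14.9, 13.3 and 16.2 in Ctrl, and 13.5, 7.79 and 12.0 in WT. Against Ctrl the ratio of means in Arid1a_Het was 0.490, with log2FC -0.95, SE 0.22, adjusted p = 0.299 over all genes in limma. The exact two-sided permutation p was 0.1, the smallest possible. Against WT the Arid1a_Het value had log2FC -0.53, SE 0.22, adjusted p = 0.245 and an exact p of 0.2. The WT 2 value lay within the Arid1a_Het range. Ctrl against WT gave log2FC 0.42, SE 0.22, adjusted p = 0.204 and an exact p of 0.2. The whole-gene value is a weak check of the labels, since only cells that make Cre recombine the allele and the deleted part was not read separately.

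**Figure D2:**
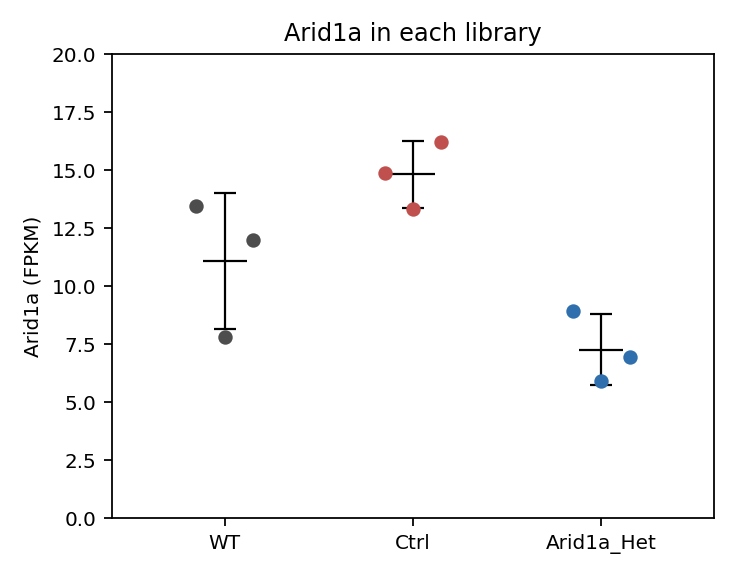
Arid1a in FPKM (linear axis) with a point per library and bars for mean ± SD of 3 libraries in WT, Ctrl and Arid1a_Het. The 3 Arid1a_Het libraries lie below the 3 Ctrl libraries, and WT 2 lies among the Arid1a_Het values.

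In Ctrl glands Reg1, Reg3b and Reg3g, which were low in WT, rose steeply, while members of the parietal and enteroendocrine lists fell. Reg1, a regenerating-family lectin of exocrine tissue (chromosome 6, 78422711 to 78428667), stood at 1329.5 ± 291 against 1.16 ± 0.524 FPKM, log2FC 9.27, SE 0.28, adjusted p = 6.06e-07. Its relatives Reg3b (183 ± 12.5 against 0.149 ± 0.138 FPKM) and Reg3g (234 ± 9.07 against 0.540 ± 0.366 FPKM), antimicrobial lectins of the gut, rose as well, with log2 fold changes of 7.33 and 7.28. Atp4b, the proton pump subunit whose promoter drives Cre (chromosome 8, 13386205 to 13396825), fell to 259 ± 174 against 3067 ± 2063 FPKM, log2FC -3.62, SE 0.96, adjusted p = 0.0443. Sst, the hormone somatostatin, fell to 13.3 ± 6.31 against 153 ± 19.4 FPKM, log2FC -3.53, SE 0.49, adjusted p = 0.00465. Atp4b missed the threshold without Arid1a_Het 1, Ctrl 1/2/3 or WT 2/3 (adjusted p = 0.0624, 0.131, 0.0640, 0.120, 0.143 and 0.0938; 0.00566 to 0.143 over 24 alternatives).

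Among the other largest increases in Ctrl were Gp2, a membrane glycoprotein of zymogen granules and M cells, with 596 ± 169.9 against 1.05 ± 1.48 FPKM, log2FC 8.38, SE 0.54, adjusted p = 9.06e-05. Cym, the milk-clotting protease chymosin, stood at 9092 ± 7157 against 34.4 ± 38.7 FPKM, log2FC 8.15, SE 1.12, adjusted p = 0.00456. The iron-binding protein gene Ltf rose by 7.35 (SE 0.82) on the log2 scale, the retinoic acid synthesis enzyme Aldh1a3 by 6.90 (SE 0.59), the annexin Anxa8 by 6.27 (SE 0.54), the GABA receptor subunit Gabrp by 5.69 (SE 0.64) and the secretoglobin Scgb3a1 by 5.54 (SE 0.45). Their adjusted p-values ran from 0.000361 for Scgb3a1 to 0.00203 for Gabrp. The largest decreases included Hamp2, a hepcidin gene, with log2FC -4.33, SE 0.91, adjusted p = 0.0218. The potassium channel Kcnj16 had log2FC -3.89, SE 0.87, adjusted p = 0.0251, and Rdh7, a retinol dehydrogenase, log2FC -3.58, SE 0.53, adjusted p = 0.00587. Cd36, a fatty acid uptake receptor, had log2FC -3.67, adjusted p = 0.0121, and Lpl, lipoprotein lipase, log2FC -3.14, adjusted p = 0.0403. Fabp3, a fatty acid carrier (log2FC -3.16, adjusted p = 0.0393), and Apoa1, an apolipoprotein (log2FC -3.70, adjusted p = 0.0243), fell too. Tnni3, a troponin best known from heart muscle, had log2FC -3.25, adjusted p = 0.0276. Reg3b and Reg3g, and Hamp2 and its close copy, share long stretches of sequence, so reads may be split between them. Lpl lost its call in 10 alternatives, Fabp3 in 9, Kcnj16 in 7, Hamp2, Apoa1 and Tnni3 in 6 and Rdh7 and Cd36 in 1 (adjusted p up to 0.134).

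Parietal cell genes fell in Ctrl in 11 of 24 cases, while 0 rose and 13 did not pass, against 17 that fell adjusted over the list alone. Relative to all genes, the median log2 change of the list was -1.72. The parietal cell list had adjusted p = 2.68e-15 and adjusted p = 0.306 with an estimated correlation. Slc26a9, a chloride transporter (log2FC -2.40, SE 0.40, adjusted p = 0.0101), and Hrh2, the histamine receptor through which acid secretion is stimulated (log2FC -2.51, SE 0.49, adjusted p = 0.0177), were among them. So were Kcnj15, a potassium channel (log2FC -3.04, SE 0.63, adjusted p = 0.0204), and Clic6, a chloride channel protein (log2FC -2.47, SE 0.51, adjusted p = 0.0207). The parietal count was 1 without Ctrl 1/3 or WT 2/3, 4 without Ctrl 2, and 2 to 18 in 4 other settings, while the list test held each time. WT 2, the library apart on the first component, had the highest mean log2 parietal level, 6.20, and Ctrl 1 the lowest, 3.57. Kcnj15 and Clic6 lost their calls in 5 alternatives and Hrh2 in 4 (adjusted p up to 0.0833).

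Enteroendocrine cell genes fell in Ctrl in 4 of 13 cases, Sst among them, and 0 rose, while 5 fell adjusted over the list alone, and the median relative to all genes was -1.79. The enteroendocrine cell list had adjusted p = 7.75e-06 and adjusted p = 0.306 with an estimated correlation. Ghrl, the hunger hormone ghrelin, stood at 25.7 ± 8.62 against 178 ± 2.11 FPKM, log2FC -2.79, SE 0.31, adjusted p = 0.00195. The vesicle protein Syp had log2FC -1.61, SE 0.31, adjusted p = 0.0160, and Chga, the granule protein chromogranin A, had log2FC -2.03, SE 0.51, adjusted p = 0.0378. Of 12 tuft cell genes, Dclk1 (log2FC -0.93, SE 0.23, adjusted p = 0.0377) and Ltc4s, a leukotriene synthase (log2FC -0.71, SE 0.18, adjusted p = 0.0413), fell. Of the same genes 1 rose and 5 fell adjusted over the list alone. The tuft cell list had adjusted p = 2.22e-05 and adjusted p = 0.439 with an estimated correlation. The enteroendocrine count was 2 without Ctrl 3, and the tuft count was 0 without Arid1a_Het 1, Ctrl 1/2/3 or WT 1/2/3, and 0 to 5 in 7 other settings, and 4 with the replicate block. In the tuft list 1 gene rose without Arid1a_Het 2, with only the 2 groups or with array weights. Of 17 surface (pit) mucous cell genes 3 rose and 5 fell, or 3 and 6 adjusted over the list alone. Their median relative to all genes was -0.92. The pit cell list had adjusted p = 7.32e-05 and adjusted p = 0.306 with an estimated correlation. Psca, a surface antigen of pit cells (log2FC -1.69, adjusted p = 0.00998), and the calpain Capn9 (log2FC -1.91, adjusted p = 0.0138) fell, and the keratin Krt20 (log2FC 2.12, adjusted p = 0.0113) rose. The pit count that fell was 1 without Ctrl 2, 2 without Ctrl 3 or WT 1/2/3, 3 without Arid1a_Het 1 or Ctrl 1, and 1 to 8 in 4 other settings, and the count that rose 1 without Ctrl 3. The pit list did not pass with quantile normalization (adjusted p = 0.342). Dclk1 lost its call in 11 alternatives, Ltc4s in 10, Chga in 9, Psca and Capn9 in 2 and Syp and Krt20 in 1 (adjusted p up to 0.166).

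Chief cell genes passed only as a list: 0 of 11 were called in limma, over all genes or adjusted over the list alone. The chief cell list had adjusted p = 0.00184 and adjusted p = 0.538 with an estimated correlation. The chitinase Chia1 had log2FC -4.33, adjusted p = 0.0891 and Pgc log2FC -1.85, adjusted p = 0.209. With the replicate block both fell (adjusted p = 0.0110 and 0.0372), 3 chief cell genes in all, and the count was 1 without Arid1a_Het 2, and 1 with only the 2 groups and 2 with array weights. The list call was lost with quantile normalization (adjusted p = 0.0684). Mucous neck cell genes (adjusted p = 0.606 and adjusted p = 0.881 with an estimated correlation) were not called as a list, and 1 of 7 rose, or 2 adjusted over the list alone, 3 with array weights and 2 with the replicate block. Intestinal markers had 0 calls of 9 and adjusted p = 0.955 on the lower side, although their median log2 change was 0.64, and the count that rose was 1 without Ctrl 2 or WT 1, and 1 to 2 in 3 other settings, and 2 with the replicate block. The count that fell was 1 with no pancreas libraries.

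Markers of spasmolytic polypeptide-expressing metaplasia (SPEM), in which corpus glands take on mucous features, rose in Ctrl: 10 of 18 rose and 0 fell, and 14 rose adjusted over the list alone. Their median relative to all genes was 1.74. The SPEM list had adjusted p = 7.69e-07 and adjusted p = 0.395 with an estimated correlation. Wfdc2, a secreted whey-acidic-protein gene, stood at 428 ± 100.4 against 36.1 ± 16.2 FPKM, log2FC 3.62, SE 0.45, adjusted p = 0.00303. Cftr, the chloride channel of ductal epithelia, had log2FC 3.91, SE 0.58, adjusted p = 0.00595. The chaperone Clu had log2FC 2.71, SE 0.38, adjusted p = 0.00498 and the mucosal scavenger Dmbt1 log2FC 3.48, SE 0.52, adjusted p = 0.00595. The SPEM count was 5 without WT 2, 6 without Ctrl 2/3, and 6 with voom.

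Notch target genes rose with the NICD transgene present: 9 of 13 rose, 0 fell, and 11 rose adjusted over the list alone. The median relative to all genes was 1.13. The Notch target list had adjusted p = 2.49e-05 and adjusted p = 0.306 with an estimated correlation. Nrarp, a Notch-induced feedback regulator (chromosome 2, 25180758 to 25183339), stood at 159 ± 42.0 against 6.85 ± 2.73 FPKM, log2FC 4.38, SE 0.32, adjusted p = 0.000208. The receptors Notch3 (log2FC 2.11, adjusted p = 0.00308) and Notch1 (log2FC 1.36, adjusted p = 0.00567) and the ligand Jag1 (log2FC 1.65, adjusted p = 0.00647) rose too, although reads of an NICD transgene may be counted to Notch1 (chromosome 2, 26457903 to 26516663). The Notch count was 5 without Ctrl 1/2/3 or WT 2.

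Inflammatory genes rose in Ctrl in 14 of 21 members, cytokine and NF-kB genes, with 0 that fell and 15 that rose adjusted over the list alone. The list median relative to all genes was 1.40. The inflammatory list had adjusted p = 2.84e-07 and adjusted p = 0.461 with an estimated correlation. The neutrophil chemokine Cxcl5 (log2FC 5.13, SE 0.56, adjusted p = 0.00188) and the cytokine Il1a (log2FC 4.18, SE 0.58, adjusted p = 0.00465) rose. So did Il1rn, the interleukin-1 receptor antagonist (log2FC 3.73, SE 0.47, adjusted p = 0.00320), and Lcn2, an iron-siderophore binding protein (log2FC 3.70, SE 0.55, adjusted p = 0.00579). The inflammatory count was 7 without Ctrl 3, and 8 with a minimum FPKM of 5. Leukocyte genes rose beside them, 6 of 17 and 10 adjusted over the list alone. The leukocyte list had adjusted p = 0.00155 and adjusted p = 0.614 with an estimated correlation. Mcpt2 stood at 266 ± 74.6 against 22.4 ± 9.01 FPKM, log2FC 3.56, SE 0.35, adjusted p = 0.00111, and its near relative Mcpt1 had log2FC 4.62, SE 0.48, adjusted p = 0.00144. S100a8 (log2FC 3.65, adjusted p = 0.0240) and S100a9 (log2FC 4.40, adjusted p = 0.0152), which are abundant in neutrophils and induced in epithelia, rose. The leukocyte count was 2 without Ctrl 2/3 or WT 3, 3 without Ctrl 1 or WT 2, and 3 to 12 in 3 other settings. Interferon response genes had 1 increase of 27, Irf1 (log2FC 1.31, adjusted p = 0.0129), also 1 adjusted over the list alone. The interferon response list had adjusted p = 0.0673 and adjusted p = 0.851 with an estimated correlation. That list passed without Ctrl 1 or WT 2/3 (adjusted p = 1.90e-05, 0.0211 and 0.00496), and in 7 of 15 other settings (adjusted p = 1.33e-05 to 0.0499), among them median-ratio scaling (0.0220) and the replicate block (0.0266). Its count was 0 without Ctrl 2/3, 2 without Ctrl 1, and 2 with no pancreas libraries, and 6 with the replicate block. MHC class II genes had 0 calls of 7 and adjusted p = 0.0681. They passed as a list without Arid1a_Het 1/3, Ctrl 3 or WT 2 (adjusted p = 0.0110, 0.0279, 0.0392 and 0.00503), and in 8 of 15 other settings (adjusted p = 0.00652 to 0.0499), among them median-ratio scaling (0.0419). The MHC count that rose was 1 without Arid1a_Het 3, and 2 with only the 2 groups and 7 with array weights. S100a8 lost its call in 7 alternatives, S100a9 in 4, Irf1 in 2 and Il1a in 1 (adjusted p up to 0.0925).

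Genes of cell division had positive log2 changes in Ctrl in 30 of 30 cell cycle and 36 of 36 DNA replication genes, but few passed singly. Of 30 cell cycle genes 1 rose, the mitotic kinesin Kif23 (log2FC 2.41, adjusted p = 0.0267), also 1 adjusted over the list alone. The median relative to all genes was 0.81. The cell cycle list had adjusted p = 0.000913 and adjusted p = 0.789 with an estimated correlation. The cell cycle count was 0 without Ctrl 1/2/3 or WT 2/3, 2 without Arid1a_Het 2, 15 without WT 1, and 0 to 15 in 3 other settings, and 9 with the replicate block. Of 36 DNA replication genes 0 were called in limma, over all genes or adjusted over the list alone, with Pold1, a polymerase subunit, at log2FC 0.87, adjusted p = 0.0743. The DNA replication list had adjusted p = 0.00856 and adjusted p = 0.851 with an estimated correlation. That call was lost without WT 2 (adjusted p = 0.113), and the count that rose was 1 without Arid1a_Het 2, and 7 with array weights. With the replicate block 5 rose, Pold1 among them (adjusted p = 0.0253). Isthmus and stem cell genes (adjusted p = 0.434 and adjusted p = 0.851 with an estimated correlation) had 1 call, Prom1 (log2FC 1.46, adjusted p = 0.0139), and 4 adjusted over the list alone. The isthmus count was 0 without Ctrl 2/3, 2 without Arid1a_Het 2/3, 4 without WT 1, and 2 to 6 in 3 other settings, and 3 with the replicate block. Of 10 Wnt target genes Myc (log2FC 1.37, adjusted p = 0.0190), Ccnd1 (log2FC 1.76, adjusted p = 0.0191) and Sox4 (log2FC 1.42, adjusted p = 0.0473) rose, also 3 adjusted over the list alone, with adjusted p = 0.628 for the list. The Wnt count was 0 without Ctrl 1/2/3 and 1 without WT 2. Sox4 lost its call in 11 alternatives, Kif23 in 7, Myc and Ccnd1 in 4 and Prom1 in 2 (adjusted p up to 0.148).

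Of 32 p53 target genes 5 rose and 7 rose adjusted over the list alone, while the list was not called. Among them were Phlda3, an inhibitor of Akt (log2FC 2.94, adjusted p = 0.00871), the kinase Plk2 (log2FC 0.94, adjusted p = 0.0218), the death receptor Tnfrsf10b (log2FC 1.43, adjusted p = 0.0240) and Psrc1 (log2FC 1.12, adjusted p = 0.0273). The p53 target list had adjusted p = 0.159 and adjusted p = 0.851 with an estimated correlation. The p53 count was 1 without Ctrl 1/2/3 or WT 2, 2 without WT 3, and 2 to 10 in 5 other settings, and 9 with the replicate block, and the count that fell 1 with quantile normalization or array weights. The p53 list passed with no filter (adjusted p = 0.0288). Immediate early and dissociation stress genes rose in 7 of 18 cases, or 12 adjusted over the list alone. The immediate early list had adjusted p = 0.00155 and adjusted p = 0.538 with an estimated correlation. The genes that rose include the heat shock genes Hspa1a (log2FC 3.09, adjusted p = 0.00278) and Hspa1b (log2FC 3.53, adjusted p = 0.00647), a near-identical pair, and Ier2 (log2FC 0.86, adjusted p = 0.00893). That count was 3 without Ctrl 2/3 or WT 3, 4 without Ctrl 1, and 2 to 13 in 4 other settings. The YAP target list had adjusted p = 0.0645 and adjusted p = 0.776 with an estimated correlation. YAP and TEAD targets had 2 increases of 17 and 6 adjusted over the list alone. Over all genes these were F3, tissue factor (log2FC 3.96, adjusted p = 0.00203), and Arhgef17 (log2FC 1.64, adjusted p = 0.0236). The YAP list passed without Arid1a_Het 2/3, Ctrl 1/2 or WT 2 (adjusted p = 0.0331, 0.0415, 0.0328, 0.0412 and 0.00911), and in 9 of 15 other settings (adjusted p = 0.0195 to 0.0499), among them median-ratio scaling (0.0404). Its count was 1 without Ctrl 1/2/3 or WT 3, 4 without WT 1, 6 without Arid1a_Het 2, and 1 to 10 in 6 other settings, and 5 with the replicate block, and the count that fell 1 with array weights. The unfolded protein response had 0 calls of 20 and adjusted p = 0.523. Its count that fell was 1 without WT 1, and 1 with array weights, and that which rose 1 with array weights and 8 with the replicate block. Psrc1 lost its call in 9 alternatives, Plk2 and Arhgef17 in 8, Tnfrsf10b in 6 and Phlda3 and Ier2 in 1 (adjusted p up to 0.105).

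Oxidative phosphorylation genes, of the mitochondrial respiratory chain, had 68 of 68 negative log2 changes in Ctrl. WT 2 had the highest mean log2 level of these and of parietal cell genes (7.20 and 6.20). Over all genes 2 fell in limma, and 0 adjusted over the list alone. The median relative to all genes was -0.77, beside -1.72 for parietal cell genes. The oxidative phosphorylation list had adjusted p = 9.62e-23 and adjusted p = 0.463 with an estimated correlation. The 2 that fell were the mitochondrial complex genes Ndufa4 (log2FC -1.13, adjusted p = 0.0399) and Ndufa10 (log2FC -0.59, adjusted p = 0.0497), and the count was 0 without Ctrl 1/2/3 or WT 2/3, 1 without Arid1a_Het 1, and 0 to 23 in 11 other settings, and 32 with the replicate block. Of 24 glycolysis and hypoxia genes 3 rose and 2 fell, the same counts as adjusted over the list alone, with adjusted p = 0.0577. Hexokinase Hk2 (log2FC 2.46, adjusted p = 0.00410) and the lactate exporter Slc16a3 (log2FC 2.16, adjusted p = 0.0140) rose, and the mitophagy receptor Bnip3 (log2FC -1.62, adjusted p = 0.00320) fell. The glycolysis list passed without Ctrl 3 or WT 1/3 (adjusted p = 0.0206, 0.0429 and 0.0112), and with a total without the 50 highest genes (adjusted p = 0.0496). Its count of increases was 1 without Ctrl 2/3, and 5 with array weights, and 5 with the replicate block. Its count of decreases was 1 without Arid1a_Het 1, Ctrl 1/2/3 or WT 1/2/3, and 1 with no filter and 4 with array weights. Cholesterol and lipid synthesis genes had 0 calls of 22, with adjusted p = 0.230 on the lower side but a median log2 change of 0.09. They passed without Ctrl 1 (adjusted p = 0.0237), and with no pancreas libraries (adjusted p = 0.0264). Their count that rose was 2 with array weights, and that which fell 1 to 2 in 4 other settings. Ndufa10 lost its call in 15 alternatives, Ndufa4 in 9 and Slc16a3 in 3 (adjusted p up to 0.155).

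In the BAF complex 1 of 24 genes fell, over all genes and adjusted over the list alone, the muscle-enriched subunit Smarcd3 (log2FC -1.88, adjusted p = 0.0274), with adjusted p = 0.523 for the list. The BAF count was 0 without Ctrl 1/2/3 or WT 2/3, and 0 in 4 other settings, and the count that rose was 4 with array weights and 2 with the replicate block. In the Polycomb complex PRC2 0 of 10 were called in limma and 4 rose adjusted over the list alone, with Rbbp7 at log2FC 0.76, adjusted p = 0.0615. The PRC2 list had adjusted p = 0.0523 and adjusted p = 0.780 with an estimated correlation. That list passed without Arid1a_Het 1/2 or WT 1/3 (adjusted p = 0.0419, 0.0449, 0.0456 and 0.0417), and in 9 of 15 other settings (adjusted p = 0.0210 to 0.0497), among them median-ratio scaling (0.0266). Its count was 1 without Arid1a_Het 3, 2 without Arid1a_Het 2, and 1 to 4 in 3 other settings, and 3 with the replicate block, Rbbp7 among them (adjusted p = 0.0348). Smarcd3 lost its call in 8 alternatives (adjusted p up to 0.108).

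Fibroblast genes had 0 calls of 13 in limma, over all genes or adjusted over the list alone, and a median relative to all genes of -1.12. The fibroblast list had adjusted p = 0.000147 and adjusted p = 0.538 with an estimated correlation. Fbln1, a matrix protein gene, had log2FC -0.92, adjusted p = 0.0516, and adjusted p = 0.00926 with the replicate block, the 1 fibroblast gene that then fell. The fibroblast count that fell was 1 without Arid1a_Het 2/3, and 1 in 3 other settings, and that which rose 1 with array weights. The fibroblast call was lost with array weights (adjusted p = 0.117). Smooth muscle genes had 0 of 5, with adjusted p = 0.0399 and adjusted p = 0.538 with an estimated correlation, and Mylk at log2FC -0.41, adjusted p = 0.195. The count that fell was 1 with no filter. The list call was lost without Ctrl 2 or WT 1/2 (adjusted p = 0.0954, 0.200 and 0.0724), and in 6 of 14 other settings (adjusted p = 0.0627 to 0.257), among them median-ratio scaling (0.178) and the replicate block (0.0627). Too few endothelial genes were tested for a list test, and Flt1, a VEGF receptor, rose (log2FC 1.84, adjusted p = 0.0196). Squamous genes of the forestomach, which borders the corpus, had 2 increases of 9, Ivl (log2FC 4.17, adjusted p = 0.0163) and Sprr1a (log2FC 2.30, adjusted p = 0.0241), also 2 adjusted over the list alone. The squamous list had adjusted p = 0.348 and passed without WT 1 (adjusted p = 0.0247), and with voom (adjusted p = 0.0483). The squamous count was 0 without Ctrl 3 or WT 2/3, 1 without Ctrl 2, 4 without WT 1, and 0 with voom and 1 with no filter. Exocrine pancreas genes had 0 calls of 5 and adjusted p = 0.870 on the lower side, with a median log2 change of 0.96. They passed with no pancreas libraries (adjusted p = 0.0137). Flt1 and Sprr1a lost their calls in 6 alternatives and Ivl in 4 (adjusted p up to 0.114).

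Across the 11209 genes tested, 1127 differed between Ctrl and WT, 786 higher and 341 lower in Ctrl, and 810 of these changed at least 2-fold. The groups did not overlap at 43.7% of genes. Splits into 3 and 3 average 10%, with a spread not tested. The median of all genes lay at 0.24 (log2), and at 0.01 after median-ratio scaling. That scaling moved the split to 608 higher and 587 lower of 1195, with 887 genes called the same way by both, and quantile normalization gave 568 higher and 703 lower of 1271. The count was 400 without Ctrl 1/2 or WT 2, 260 without Ctrl 3 and 414 without WT 3, and 707 with no pancreas libraries. With the replicate block it was 2473, 1804 higher and 669 lower. Of 72 named calls, leaving out Ctrl 1/2/3 or WT 2/3 ended 26, 26, 36, 27 and 27, and leaving out Arid1a_Het 1 or WT 1 ended 6 and 4.

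**Figure D3:**
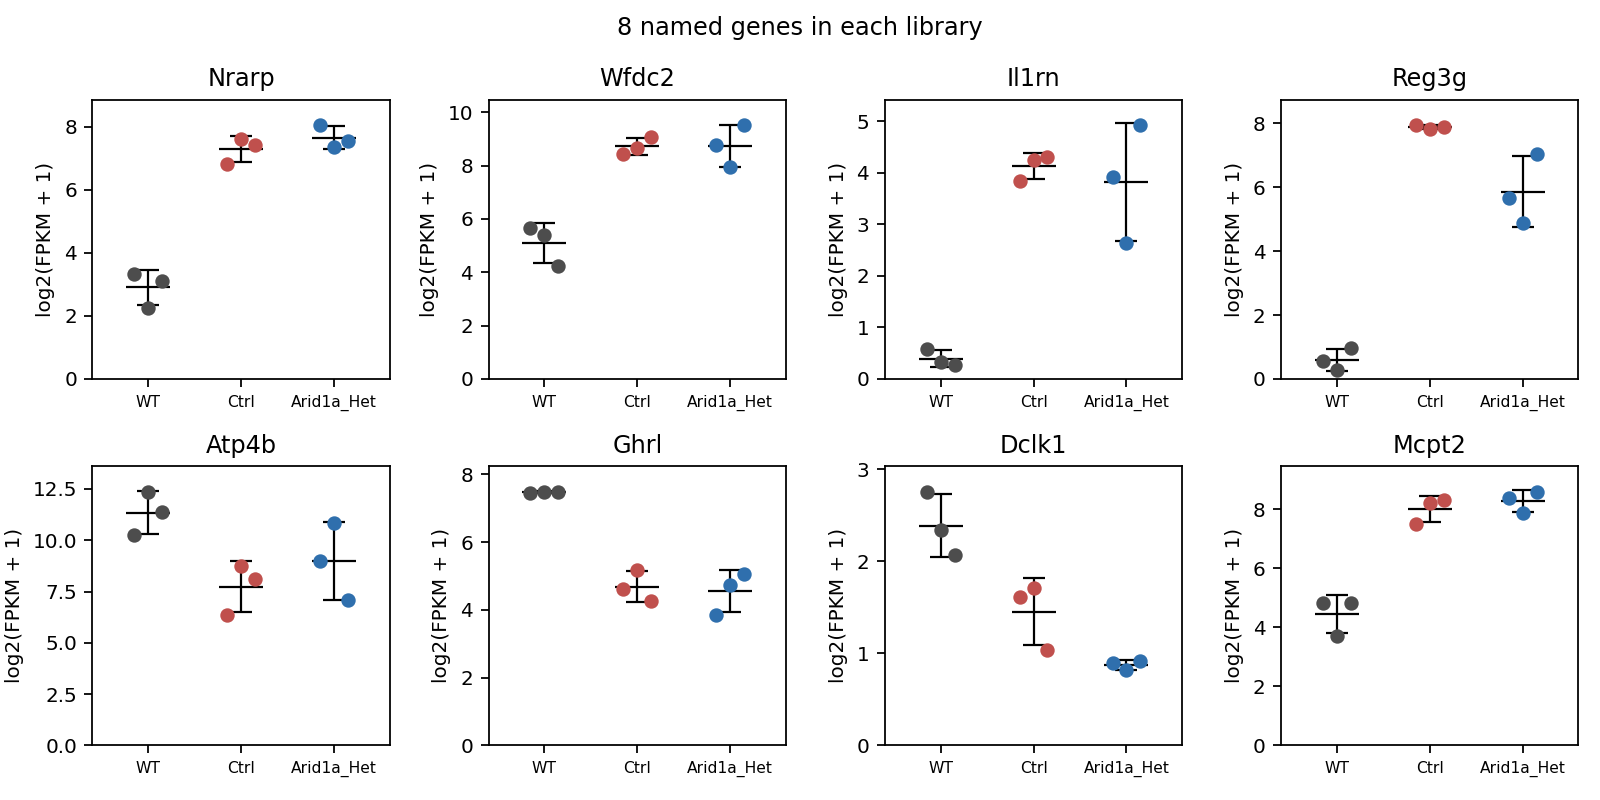
log2(FPKM + 1) of 8 genes (linear axes that start at 0) with a point per library and bars for mean ± SD of 3 libraries in WT, Ctrl and Arid1a_Het. Nrarp, Wfdc2, Il1rn, Reg3g and Mcpt2 are higher in both transgenic groups than in WT, and Ghrl and Dclk1 are lower, and Atp4b fell in Ctrl.

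Loss of a copy of Arid1a on top of NICD left no protein-coding gene past the threshold in limma. Only Mir7688, a microRNA locus at chromosome 10, 93433107 to 93433162, was called, and it was singled out after its values were seen. It held 0 reads in each Arid1a_Het library against 13, 14 and 13 in Ctrl and 1, 0 and 0 in WT (adjusted p = 0.00127). The unadjusted count at p under 0.05 was 1305 of 11209 genes. Limma voom on whole reads called 0, with 1364 at unadjusted p under 0.05. The call rests on few reads at a locus of the class that was higher throughout the Ctrl libraries. Mir7688 lost its call in 3 alternatives (adjusted p up to 0.401).

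Genes of lowest p on the higher side in Arid1a_Het, none of them past the threshold, were the interferon-induced GTPase Gbp2b (log2FC 2.32, SE 0.36, adjusted p = 0.187), the cytochrome P450 Cyp2s1 (log2FC 1.12, SE 0.22, adjusted p = 0.241), the membrane protein gene Prom2 (log2FC 1.34, SE 0.27, adjusted p = 0.250), Paqr7 (log2FC 1.34, SE 0.28, adjusted p = 0.264) and the quinone reductase Nqo1 (log2FC 1.09, SE 0.24, adjusted p = 0.280). On the lower side they were the superoxide-generating oxidase Nox1 (log2FC -1.59, SE 0.21, adjusted p = 0.119), AA465934 (log2FC -2.64, SE 0.38, adjusted p = 0.143), the G protein subunit Gnb5 (log2FC -1.05, SE 0.16, adjusted p = 0.161), the small RNA host gene Snhg9 (log2FC -1.12, SE 0.19, adjusted p = 0.223) and Vipr1, a receptor of vasoactive intestinal peptide (log2FC -0.98, SE 0.17, adjusted p = 0.223). Nox1 passed in 3 and AA465934 in 2 alternatives.

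Of 30 gene lists 13 were called by camera in Arid1a_Het against Ctrl, while 0 members of any list passed the gene test in limma with all 9 libraries. Parietal cell genes were on the higher side in 23 of 24. The median relative to all genes was 0.65. The parietal cell list had adjusted p = 5.89e-10 and adjusted p = 0.770 with an estimated correlation. Single parietal genes such as the water channel Aqp4 (log2FC 1.29, adjusted p = 0.434) and Kcnj15 (log2FC 1.16, adjusted p = 0.482) did not pass, nor did any adjusted over the list alone. Surface mucous cell genes had adjusted p = 1.26e-07 and adjusted p = 0.384 with an estimated correlation. In that list 1 member rose adjusted over the list alone. Psca had log2FC 1.17, adjusted p = 0.332 and Capn9 log2FC 1.20, adjusted p = 0.381. The pit call was lost with quantile normalization (adjusted p = 0.192). Chief cell genes had adjusted p = 0.0210 and adjusted p = 0.840 with an estimated correlation. Pgc was at log2FC 1.17, adjusted p = 0.619 and Lgr5, a receptor of stem and chief cells, at log2FC -0.44, adjusted p = 0.517. The chief cell call was lost without Arid1a_Het 2 or Ctrl 3 (adjusted p = 0.754 and 0.134), and with median-ratio scaling, quantile normalization, array weights or voom (adjusted p = 0.232, 0.583, 0.210 and 0.270). Arid1a_Het 2 had the highest mean log2 chief cell level, 5.80.

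Oxidative phosphorylation genes were higher in Arid1a_Het than in Ctrl in 63 of 68, with a median relative to all genes of 0.39, beside 0.65 for parietal cell genes. The oxidative phosphorylation list had adjusted p = 2.59e-15 and adjusted p = 0.840 with an estimated correlation. Sdhc (log2FC 0.32, adjusted p = 0.526) and Ndufs5, which lay on the other side (log2FC -0.65, adjusted p = 0.458), did not pass. Interferon response genes were on the same side, with 21 of 27 positive. The interferon response list had adjusted p = 4.22e-06 and adjusted p = 0.840 with an estimated correlation. The ubiquitin-like protein Isg15 had log2FC 1.19, adjusted p = 0.506 but the transcription factor Irf1 log2FC -0.48, adjusted p = 0.443. The interferon call was lost without Arid1a_Het 2 or Ctrl 1 (adjusted p = 0.281 and 0.245). Cholesterol and lipid synthesis genes (adjusted p = 8.02e-05 and adjusted p = 0.840 with an estimated correlation) were also on the higher side. So were glycolysis and hypoxia genes (adjusted p = 0.00123 and adjusted p = 0.770 with an estimated correlation), with Hk2 at log2FC -0.86, adjusted p = 0.404 and the carbonic anhydrase Car9 at log2FC 0.60, adjusted p = 0.443. The glycolysis call was lost with quantile normalization or no pancreas libraries (adjusted p = 0.0851 and 0.252). Among stromal markers, fibroblast genes had adjusted p = 0.000179 and adjusted p = 0.840 with an estimated correlation, with Fbln1 at log2FC 0.57, adjusted p = 0.431. That call was lost with median-ratio scaling or voom (adjusted p = 0.0867 and 0.208). Smooth muscle genes had adjusted p = 0.00591 and adjusted p = 0.770 with an estimated correlation, with Mylk at log2FC 0.44, adjusted p = 0.443. The smooth muscle call was lost without Arid1a_Het 2 or Ctrl 2 (adjusted p = 0.107 and 0.0557), and with median-ratio scaling, quantile normalization or voom (adjusted p = 0.151, 0.0536 and 0.270). In none of these 6 lists did a member pass adjusted over the list alone.

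**Figure D4:**
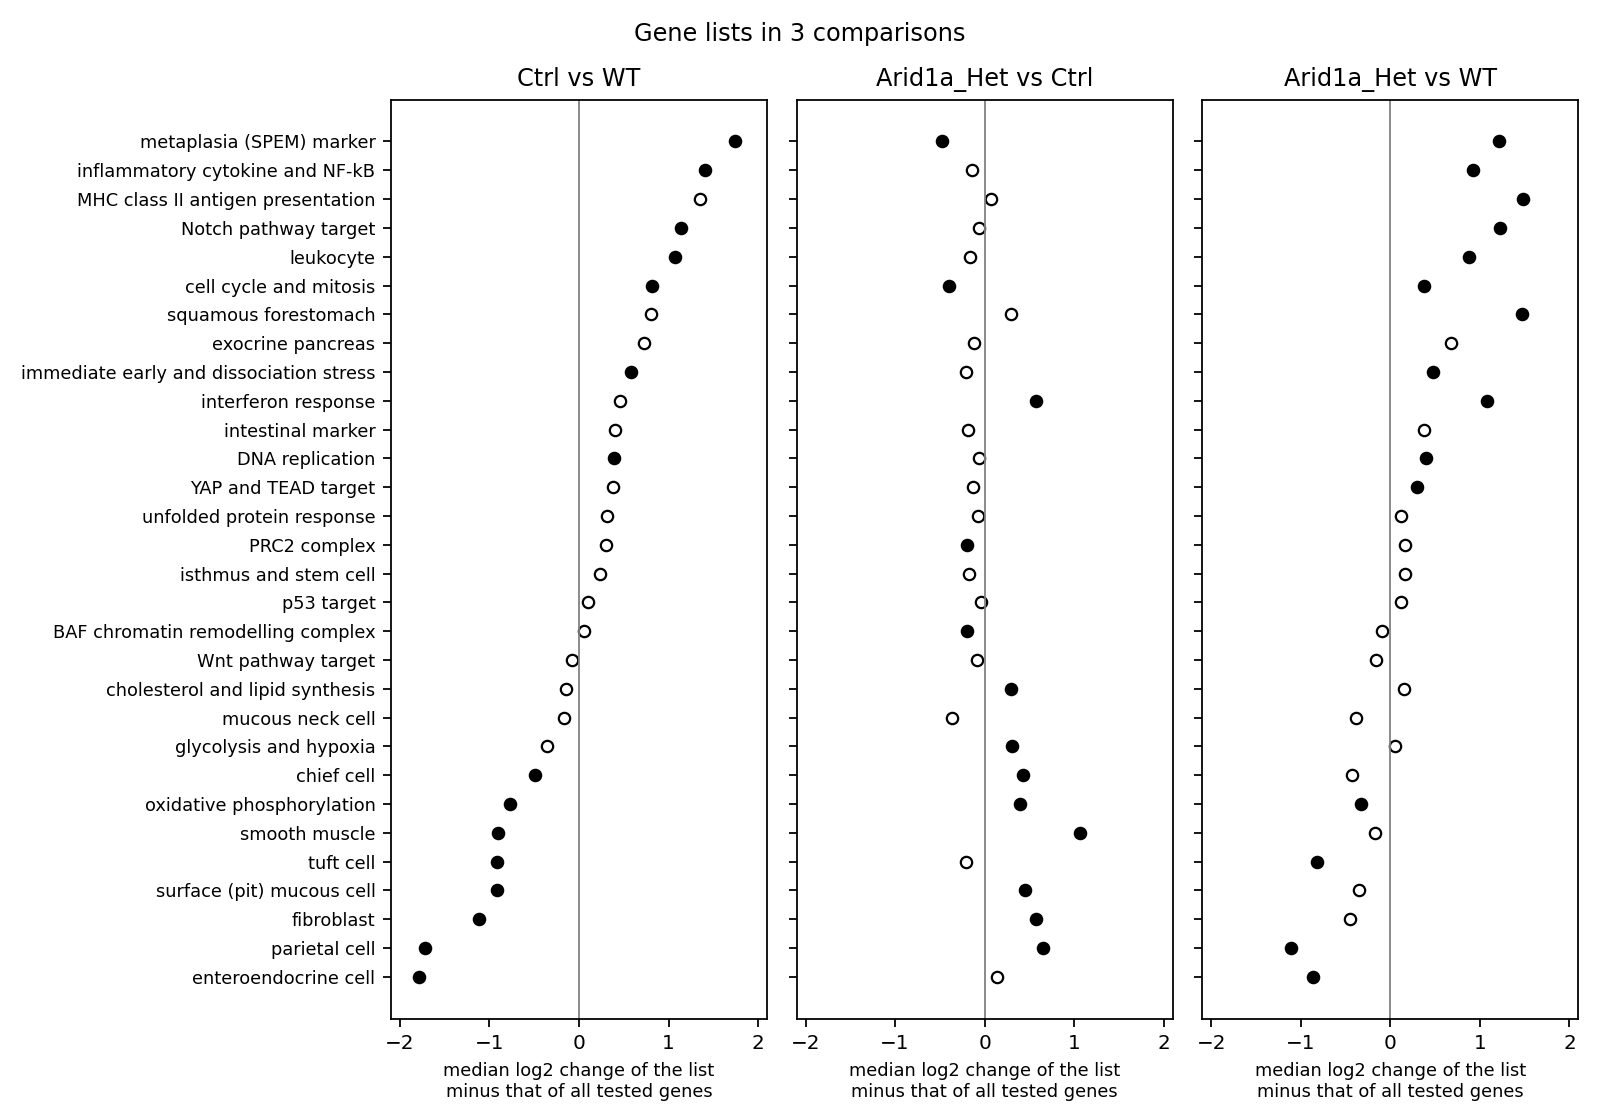
Median log2 change of each of 30 gene lists minus that of all tested genes (linear axis) in 3 comparisons, filled where camera with its preset correlation passed an adjusted p of 0.05 and otherwise open. Parietal cell and oxidative phosphorylation genes lie below 0 in both comparisons with WT and above 0 in Arid1a_Het against Ctrl, and 0 lists pass with an estimated correlation.

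On the lower side in Arid1a_Het stood the BAF complex. Its genes were negative in 22 of 24, with a median of -0.20 relative to that of all genes (-0.16). The BAF list had adjusted p = 0.0157 and adjusted p = 0.840 with an estimated correlation. Arid1a itself was the only member that fell adjusted over the list alone, and the list was not tested without it. Other subunits, such as Smarcd1 (log2FC -0.53, adjusted p = 0.383) and Brd9 (log2FC -0.58, adjusted p = 0.397), did not pass. The BAF call was lost without Arid1a_Het 3 or Ctrl 2 (adjusted p = 0.0565 and 0.0557), and with no pancreas libraries (adjusted p = 0.140). PRC2 genes had adjusted p = 0.0484 and adjusted p = 0.840 with an estimated correlation, with Phf1 at log2FC -0.94, adjusted p = 0.361 and Ezh1 at log2FC -0.63, adjusted p = 0.403. The PRC2 call ended without Arid1a_Het 2/3, Ctrl 1/2 or WT 2/3 (adjusted p = 0.211, 0.0534, 0.0577, 0.0829, 0.0503 and 0.0520), and in 7 of 14 other settings (adjusted p = 0.0527 to 0.0749), among them median-ratio scaling (0.0591). Cell cycle genes were negative in 30 of 30, with a median relative to all genes of -0.40. The cell cycle list had adjusted p = 0.0229 and adjusted p = 0.935 with an estimated correlation. Cenpf was at log2FC -1.06, adjusted p = 0.404 and the proliferation marker Mki67 at log2FC -1.52, adjusted p = 0.475. That list did not pass without Arid1a_Het 2/3 or Ctrl 2 (adjusted p = 0.211, 0.0509 and 0.0557), nor with a pseudocount of 0.1 or 0.01 or no pancreas libraries (adjusted p = 0.0800, 0.0984 and 0.0521). SPEM markers were negative in 17 of 18, with adjusted p = 0.0428 and adjusted p = 0.840 with an estimated correlation. Ceacam10 was at log2FC -1.11, adjusted p = 0.395, Dmbt1 at log2FC -1.59, adjusted p = 0.397 and the transcription factor Sox9 at log2FC -0.58, adjusted p = 0.403. The SPEM call ended without Arid1a_Het 1/2, Ctrl 2/3 or WT 2 (adjusted p = 0.191, 0.297, 0.0557, 0.149 and 0.115), and with a pseudocount of 0.1 or 0.01, only the 2 groups or array weights (adjusted p = 0.0759, 0.0827, 0.0713 and 0.254).

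Notch and p53 targets were not called between Arid1a_Het and Ctrl. Of 13 Notch targets 0 were called in limma, over all genes or adjusted over the list alone. The Notch target list had adjusted p = 0.865 and adjusted p = 0.983 with an estimated correlation, a test on the higher side beside a median log2 change of -0.23. The target Myc was at log2FC -0.71, adjusted p = 0.404 and Hey1 at log2FC 0.77, adjusted p = 0.444. Of 32 p53 targets 0 were called in either way, with the adjusted p-values of the Notch list. The damage sensor Ddb2 was at log2FC -0.66, adjusted p = 0.404, Tigar at log2FC -0.56, adjusted p = 0.404, the p53 ubiquitin ligase Mdm2 at log2FC -0.53, adjusted p = 0.414 and Ccng1 at log2FC 0.32, adjusted p = 0.414. Tuft cell genes were not called as a list (adjusted p = 0.0824), but Rgs13 (log2FC -1.23, adjusted p = 0.223) fell when adjusted over that list alone. So did Hspa1a (log2FC -1.89, adjusted p = 0.231) in the immediate early list (adjusted p = 0.127) and 2 of 4 genes of the sex check. Inflammatory genes (adjusted p = 0.123) held 0 calls of 21 in either way, with Nfkbiz at log2FC -1.17, adjusted p = 0.352. The tuft list passed without Ctrl 3 (adjusted p = 0.000110), and with a pseudocount of 0.01 or array weights (adjusted p = 0.0473 and 0.0214). The inflammatory list passed without Arid1a_Het 3 or Ctrl 1 (adjusted p = 6.71e-07 and 0.0202), and with quantile normalization or no pancreas libraries (adjusted p = 0.0451 and 7.56e-10). Its count that fell was 3 without Arid1a_Het 3 and 4 with no pancreas libraries. Leukocyte genes were not called (adjusted p = 0.794, higher side), but fell with no pancreas libraries (adjusted p = 0.000369, 2 genes). The immediate early list passed without Ctrl 1 (adjusted p = 0.0279), and with quantile normalization or no pancreas libraries (adjusted p = 0.00585 and 0.00669). Its count that fell was 1 without Arid1a_Het 3.

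Against Ctrl the median of all genes in Arid1a_Het was -0.16 (log2) and 0.02 after median-ratio scaling. The groups did not overlap at 24.7% of genes, where splits average 10% (spread untested). The gene count was 22 without Arid1a_Het 3, 3 without WT 3, 2 without Arid1a_Het 1, and 21 with no pancreas libraries. The list count was 8 without Arid1a_Het 2 or without Ctrl 2.

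With both changes present, Arid1a_Het glands differed from WT in many of the genes that also differed in Ctrl. Reg1 stood at 646 ± 196 against 1.16 ± 0.524 FPKM, log2FC 8.20, SE 0.28, adjusted p = 1.88e-06, and Reg3g at 69.5 ± 54.0 against 0.540 ± 0.366 FPKM, log2FC 5.26, SE 0.45, adjusted p = 0.000792. The Notch feedback gene Nrarp stood at 203 ± 53.7 against 6.85 ± 2.73 FPKM, log2FC 4.74, SE 0.32, adjusted p = 0.000339. Sst (log2FC -3.25, SE 0.49, adjusted p = 0.0113) and Ghrl (log2FC -2.93, SE 0.31, adjusted p = 0.00238), hormones of gastric endocrine cells, fell. So did the tuft cell gene Rgs13 (log2FC -1.88, SE 0.21, adjusted p = 0.00308).

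Further increases among the largest in Arid1a_Het were Gp2 (7.50 (SE 0.54) on the log2 scale), Aldh1a3 (6.69 (SE 0.59)), Ltf (6.48 (SE 0.82)), Anxa8 (6.37 (SE 0.54)), Cym (5.93 (SE 1.12)), the serine protease Prss22 (5.43 (SE 0.47)), Gabrp (5.41 (SE 0.64)) and Reg3b (4.89 (SE 0.45)). Their adjusted p-values ran from 0.000430 for Gp2 to 0.0274 for Cym. Further decreases were the cystatin Cst8 (log2FC -2.90, adjusted p = 0.0126), the retinol dehydrogenase Rdh7 (log2FC -2.67, adjusted p = 0.0321), the Ras activator Rasgrp3 (log2FC -2.60, adjusted p = 0.0315), the synaptotagmin Syt7 (log2FC -2.19, adjusted p = 0.0274). Others were Slc26a9 (log2FC -1.98, adjusted p = 0.0353), the retinol dehydrogenase relative Sdr9c7 (log2FC -1.89, adjusted p = 0.0424) and the kinase Cdkl1 (log2FC -1.85, adjusted p = 0.00334). Sdr9c7 lost its call in 17 alternatives, Rdh7, Rasgrp3 and Slc26a9 in 13, Syt7 in 8, Cym in 6, Cst8 in 5 and Ltf and Gabrp in 1 (adjusted p up to 0.207).

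Notch targets rose in 7 of 13 cases and in 8 adjusted over the list alone. The Notch target list had adjusted p = 1.55e-07 and adjusted p = 0.422 with an estimated correlation. Among the genes that rose were Notch3 (log2FC 2.30, adjusted p = 0.00307), Notch1 (log2FC 1.25, adjusted p = 0.0140) and the transcriptional repressor Hes1 (log2FC 1.14, adjusted p = 0.0192). That count was 2 without Arid1a_Het 1, 3 without Arid1a_Het 3 or WT 1/2/3, 4 without Ctrl 2, and 2 to 4 in 3 other settings. SPEM markers rose in 3 of 18 cases and in 8 adjusted over the list alone. The SPEM list had adjusted p = 2.77e-07 and adjusted p = 0.422 with an estimated correlation. Those over all genes were Wfdc2 (log2FC 3.65, adjusted p = 0.00361), Clu (log2FC 2.51, adjusted p = 0.0119) and Cftr (log2FC 3.11, adjusted p = 0.0274). Their count was 1 without Arid1a_Het 1 or WT 3, 9 without Arid1a_Het 2, and 1 with no filter and 7 with array weights. Inflammatory genes rose in 5 of 21 cases and in 12 adjusted over the list alone. The inflammatory list had adjusted p = 3.30e-09 and adjusted p = 0.422 with an estimated correlation. Over all genes they included Il1rn (log2FC 3.43, adjusted p = 0.00701), Cxcl5 (log2FC 3.76, adjusted p = 0.0113), Il1a (log2FC 3.73, adjusted p = 0.0126) and the chemokine Cxcl16 (log2FC 1.61, adjusted p = 0.0274). The inflammatory count was 1 without WT 3, 2 without Arid1a_Het 1, 3 without Arid1a_Het 3 or WT 1, 9 without Arid1a_Het 2, and 1 to 9 in 6 other settings. Cxcl16 lost its call in 10 alternatives, Cftr in 9, Hes1 in 6, Notch1 and Il1a in 4, Clu and Cxcl5 in 3 and Il1rn in 1 (adjusted p up to 0.134).

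Tuft cell genes fell in 5 of 12 cases in Arid1a_Het and in 9 adjusted over the list alone. The median relative to all genes was -0.82. The tuft cell list had adjusted p = 5.16e-08 and adjusted p = 0.422 with an estimated correlation. Dclk1, a kinase used as a tuft cell marker (log2FC -1.51, SE 0.23, adjusted p = 0.0126), the taste cation channel Trpm5 (log2FC -1.43, SE 0.24, adjusted p = 0.0170) and the taste G protein Gnat3 (log2FC -1.23, SE 0.25, adjusted p = 0.0353) were among them. The tuft count was 1 without Arid1a_Het 1, 2 without WT 1/2, 3 without Arid1a_Het 2/3, Ctrl 1 or WT 3, and 1 to 3 in 4 other settings, and the count that rose was 1 without Arid1a_Het 2. Enteroendocrine genes fell in 2 of 13 cases, Ghrl and Sst, and in 4 adjusted over the list alone. The enteroendocrine cell list had adjusted p = 1.58e-05 and adjusted p = 0.422 with an estimated correlation. Parietal cell genes had 1 decrease of 24, Slc26a9, against 11 adjusted over the list alone. The parietal cell list had adjusted p = 1.38e-07 and adjusted p = 0.608 with an estimated correlation. Hrh2 was at log2FC -1.99, adjusted p = 0.0713. The parietal count was 0 without Arid1a_Het 1/3, Ctrl 1/2/3 or WT 2/3, 2 without WT 1, 7 without Arid1a_Het 2, and 0 in 6 other settings. Chief cell genes were not called (adjusted p = 0.0795), but passed without Arid1a_Het 2 or WT 1 (adjusted p = 0.000215 and 0.00238) and with array weights (adjusted p = 0.0478), and Chia1 stood at log2FC -3.19, adjusted p = 0.315. Surface mucous cell genes were not called as a list (adjusted p = 0.318), while 2 of 17 rose over all genes and 3 adjusted over the list alone. The mucin Muc1 (log2FC 0.98, adjusted p = 0.0193) was among them, and Krt20 was at log2FC 1.48, adjusted p = 0.0699. The pit count was 0 without Arid1a_Het 3 or WT 3, 1 without Arid1a_Het 1 or WT 1, and 0 in 3 other settings, and the count that fell was 1 without Ctrl 2. Gnat3 lost its call in 11 alternatives, Muc1 in 9, Trpm5 in 6 and Dclk1 in 2 (adjusted p up to 0.137).

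Immune genes lay on the higher side in Arid1a_Het against WT. Leukocyte genes rose in 2 of 17 cases, Mcpt1 (log2FC 4.43, adjusted p = 0.00246) and Mcpt2 (log2FC 3.84, adjusted p = 0.000969), and in 5 adjusted over the list alone. The leukocyte list had adjusted p = 8.96e-06 and adjusted p = 0.608 with an estimated correlation. Interferon response genes had 27 of 27 positive log2 changes, a median relative to all genes of 1.08 and adjusted p = 5.16e-08 and adjusted p = 0.658 with an estimated correlation. Of these genes 0 passed in limma, over all genes or adjusted over the list alone, with Irf1 at log2FC 0.83, adjusted p = 0.102, and the count that rose was 1 with no pancreas libraries. MHC class II genes were likewise positive in 7 of 7 with 0 calls in either way and adjusted p = 0.00339 and adjusted p = 0.664 with an estimated correlation, with Cd74 at log2FC 1.66, adjusted p = 0.296. That call was lost without Arid1a_Het 2 or WT 3 (adjusted p = 0.0612 and 0.0611). Squamous forestomach genes had 0 calls of 9 over all genes, and 2 adjusted over the list alone. The squamous list had adjusted p = 0.00744 and adjusted p = 0.664 with an estimated correlation, lost without WT 3 (adjusted p = 0.116), and with no filter (adjusted p = 0.140). Sprr1a was at log2FC 2.18, adjusted p = 0.0551, and the squamous count was 1 without Ctrl 3, 2 without Arid1a_Het 2 or WT 1, and 1 to 2 in 3 other settings. Smooth muscle genes were not called (adjusted p = 0.780), nor were fibroblast genes (adjusted p = 0.111), which passed without Arid1a_Het 2/3 or WT 3 (adjusted p = 0.0226, 0.00449 and 2.56e-06) and with no pancreas libraries (adjusted p = 0.00390). The endothelial gene Flt1 rose (log2FC 1.96, adjusted p = 0.0291). Flt1 lost its call in 12 alternatives (adjusted p up to 0.139).

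In Arid1a_Het against WT, oxidative phosphorylation genes had 0 calls of 68 in limma, over all genes or adjusted over the list alone. The oxidative phosphorylation list had adjusted p = 6.13e-09 and adjusted p = 0.722 with an estimated correlation. Ndufs1 was at log2FC -0.58, adjusted p = 0.0844, and the count that fell was 1 with array weights. That list did not pass without WT 2 (adjusted p = 0.381). Cell cycle genes had adjusted p = 0.0194 and adjusted p = 0.901 with an estimated correlation, with Kif23 at log2FC 1.70, adjusted p = 0.141, and did not pass without Arid1a_Het 1 or WT 2 (adjusted p = 0.127 and 0.934), nor with array weights (adjusted p = 0.0674). DNA replication genes had adjusted p = 0.00136 and adjusted p = 0.885 with an estimated correlation, with E2f1 at log2FC 0.59, adjusted p = 0.323, and did not pass without WT 2 (adjusted p = 0.335). Both lists held 0 calls in either way, but 1 cell cycle gene rose without Arid1a_Het 2 or with array weights. YAP and TEAD targets rose in 2 of 17 cases, F3 (log2FC 3.67, adjusted p = 0.00377) and the matricellular gene Ctgf (log2FC 2.70, adjusted p = 0.0304), and in 3 adjusted over the list alone. The YAP target list had adjusted p = 0.0256 and adjusted p = 0.722 with an estimated correlation, lost without WT 3 (adjusted p = 0.118), and with median-ratio scaling, quantile normalization or voom (adjusted p = 0.0581, 0.0625 and 0.0733). The YAP count was 1 without Arid1a_Het 1/3, Ctrl 1/2/3 or WT 1/3, 4 without Arid1a_Het 2, and 1 to 5 in 6 other settings. Immediate early genes had 1 increase of 18, Ier2 (log2FC 0.68, adjusted p = 0.0368), and 5 adjusted over the list alone. The immediate early list had adjusted p = 0.00174 and adjusted p = 0.654 with an estimated correlation, lost without WT 3 (adjusted p = 0.0702). The immediate early count was 0 without Arid1a_Het 1/3, Ctrl 1/2 or WT 2/3, 3 without Arid1a_Het 2, and 0 to 7 in 6 other settings. Ctgf and Ier2 lost their calls in 12 alternatives (adjusted p up to 0.214).

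Lists not called in Arid1a_Het against WT held a few calls. Of the p53 targets (32 genes, adjusted p = 0.107) Phlda3 rose (log2FC 3.36, adjusted p = 0.00849), with 2 adjusted over the list alone, and the list passed without Arid1a_Het 2 (adjusted p = 0.0455), and with no filter, a minimum FPKM of 5 or array weights (adjusted p = 0.0140, 0.0241 and 0.0453). The p53 count was 2 without WT 1, 3 without Arid1a_Het 2, and 2 with median-ratio scaling or array weights, and the count that fell 1 with median-ratio scaling or quantile normalization. Ccnd1 (log2FC 1.82, adjusted p = 0.0315) in the Wnt list (adjusted p = 0.995) and Prom1 (log2FC 1.23, adjusted p = 0.0437) in the isthmus list (adjusted p = 0.345) rose, also 1 each adjusted over the list alone. The Wnt count was 0 without Arid1a_Het 1/3, Ctrl 1/2/3 or WT 1/2/3, and 0 in 3 other settings. The isthmus count was 0 without Arid1a_Het 1/2/3, Ctrl 1/2/3 or WT 2/3, and 0 in 4 other settings. In the glycolysis and hypoxia list (adjusted p = 0.777) Slc16a3 (log2FC 2.22, adjusted p = 0.0222) and Hk2 (log2FC 1.60, adjusted p = 0.0360) rose and Bnip3 (log2FC -1.70, adjusted p = 0.00347) fell, or 3 and 1 adjusted over the list alone. The count that rose was 0 without Arid1a_Het 1 or WT 1/3, 1 without Ctrl 2/3 or WT 2, and 0 to 1 in 4 other settings. BAF genes (24, adjusted p = 0.184) and PRC2 genes (10, adjusted p = 0.476) held 0 calls in limma in either way, with Smarcd3 at log2FC -1.48, adjusted p = 0.106 and Ezh2 at log2FC 0.33, adjusted p = 0.647. The BAF list passed without WT 2 (adjusted p = 0.0136), and with array weights (adjusted p = 0.0400). The BAF count that fell was 1 without Arid1a_Het 2 or WT 1. Prom1 and Hk2 lost their calls in 12 alternatives, Ccnd1 in 11, Slc16a3 in 6 and Phlda3 in 1 (adjusted p up to 0.171).

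Across all genes, 308 differed between Arid1a_Het and WT, 231 higher and 77 lower. The groups did not overlap at 19.2% of genes, where splits average 10% (spread untested). Median-ratio scaling gave 277 higher and 86 lower of 363. The count was 91, 720 and 163 without Arid1a_Het 1/2/3, 186 and 182 without Ctrl 1/2, 130 and 95 without WT 2/3, and 115 with no pancreas libraries. Of 47 named calls, leaving out Arid1a_Het 1/2/3 ended 23, 2 and 16, leaving out Ctrl 1/2/3 ended 11, 11 and 10, and leaving out WT 1/2/3 ended 14, 15 and 22.

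The genes changed against WT overlapped between the transgenic groups. Of 231 genes higher in Arid1a_Het, 222 were also among the 786 higher in Ctrl, where independent lists would share 16.2. Of 77 lower genes 55 were also among the 341 lower in Ctrl, where independent lists would share 2.34, and 0 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.86 and a covariance of 0.379. Unchanged groups simulated against the same WT libraries gave a mean correlation of 0.47 (95% of draws from -0.43 to 0.94) and a mean covariance of 0.0456 (from -0.0262 to 0.154). The covariance exceeded the simulated mean by 0.334. With the assumed pairs of same-numbered WT and Ctrl libraries drawn together the mean covariance was 0.0419 (from -0.00634 to 0.143). Part of the excess in shared calls may come from the shared WT libraries, which are too few to be split.

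Changes in Arid1a_Het against Ctrl ran against those in Ctrl against WT, with a correlation of -0.57 and a covariance of -0.155. Unchanged groups that share the Ctrl libraries gave a mean of -0.46 and a mean covariance of -0.0462 (95% of draws from -0.169 to 0.0262), a range that holds the observed covariance. With the assumed pairs drawn together the mean covariance was -0.0241 (from -0.104 to 0.0211), a range that does not. The pairing was taken from these data, so the narrower range cannot decide. The only gene called in both, Mir7688, was higher in Ctrl than in WT or Arid1a_Het.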

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

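The array weights method used here was, like the fits added above, chosen after the data were seen. Of 25 alternatives, 16 kept the count of Ctrl against WT (1127) within 1.5 times, 11 that of Arid1a_Het against Ctrl (1) and 13 that of Arid1a_Het against WT (308); the cause of the moves was not tested except where libraries or genes were left out by construction. For Ctrl against WT the count was 748 with a minimum FPKM of 5, 3258 with array weights, 707 without Ctrl 1 and Arid1a_Het 3, and 260 to 1465 with 1 library left out. For Arid1a_Het against Ctrl it was 0 in limma with a pseudocount of 0.1 or 0.01, with voom and without small RNA genes (1198, 1155, 1364 and 1236 genes at unadjusted p under 0.05), 2 with a minimum FPKM of 5 or quantile normalization, 4 with no filter or with array weights, 5 with only the 2 groups compared, 21 without Ctrl 1 and Arid1a_Het 3, and 1 to 22 with 1 library left out. For Arid1a_Het against WT it was 140 with no filter, 105 with only the 2 groups compared, 737 with array weights, 115 without Ctrl 1 and Arid1a_Het 3, and 91 to 720 with 1 library left out. Array weights by the default method did not converge and gave 5710, 7 and 1384 genes; the gene by gene method replaced it after these counts were seen. With an estimated correlation 0 lists passed by camera in each comparison (lowest adjusted p 0.306, 0.384 and 0.422; 4, 1 and 3 lists at unadjusted p under 0.05), and with 1 library left out 15 to 18, 8 to 16 and 12 to 18 lists passed. With the replicate number as a block the counts were 2473, 2 and 691 genes, and among the named genes and lists of Ctrl against WT no call changed other than those given with their values. Arid1a_Het libraries were not taken as paired, as their correlations of deviations went both ways (0.25, 0.56 and -0.28 with WT, -0.15, 0.47 and -0.02 with Ctrl). Only 3 of 9 libraries matched their own number best, so the pairing of WT and Ctrl is uncertain too. Arid1a kept its direction and missed the threshold in all 24 alternatives of each comparison, and the correlations between comparisons stayed between 0.80 and 0.90 and between -0.72 and -0.32. The 179 named gene results had 4265 alternative values: 3763 with the call kept as passed or not passed, 458 no longer past the threshold, 44 newly past it and 0 of opposite sign. Over all 422 results of the naming rule, 105 of 10018 values had the opposite sign, in 37 results of which 0 were past the threshold; these are not named. Depth limits small RNA loci such as Mir7688.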

Other observations

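Of what follows, the gene family test, the tests of pancreas and of genomic DNA and the choice of the 3 patterns were made after the results were seen, and the tests of host genes, introns, mast cells and other splits were written before theirs. Grouped by symbol stem, 184 families of at least 8 tested members were set against the 8886 tested genes with such a stem. In Ctrl against WT, the family of interleukins and their receptors rose in 13 of 32 members where 2.11 were expected (adjusted p = 1.53e-05, one-sided exact test; 10 of 32 after median-ratio scaling). They include the alarmin Il33 and its receptor Il1rl1, the interleukin-18 receptor Il18r1, the interleukin-4 receptor Il4ra and Il1b. The interleukin count was 4 without Ctrl 3 and 5 without WT 2, where the family did not pass (adjusted p = 0.226 and 0.112), and 6 without Ctrl 1, Ctrl 2 or WT 3. CXC chemokines rose in 6 of 8 members (adjusted p = 0.000365; 5 scaled), and in 3 without Ctrl 3 (adjusted p = 0.0819). Both overlap in part with the inflammatory list. Tumour necrosis factor receptors (6 of 12 higher) and solute carriers (19 of 201 lower) passed too, but not when Ctrl 1, Ctrl 2, Ctrl 3, WT 2 or WT 3 was left out. The exact test takes members as independent: by camera in limma with an estimated correlation 0 families passed (lowest adjusted p 0.979; 2 at unadjusted p under 0.05). In Arid1a_Het against WT 0 families passed by the exact test, with a lowest adjusted p of 0.0933 and, for interleukins, 5 of 32 members higher.

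Small RNA loci were 2.53 times as high in RPM in Ctrl as in WT. Of 143 tested loci 128 had positive changes in Ctrl against WT and 10 in Arid1a_Het against Ctrl, where the only call was Mir7688. Higher output of the genes that host them is argued against as the whole cause, since in Ctrl against Arid1a_Het 28 loci exceeded their 24 hosts by a median log2 of 0.94 (95% bootstrap interval 0.56 to 1.53). Carried-over genomic DNA cannot be told apart from its absence: olfactory receptor genes, silent here, gained in the same comparison 0.0849 of the RPM that a small RNA locus gained over all 441 loci (interval -0.00651 to 0.638), where 0.333 was asked for. All 3 Ctrl libraries held more olfactory reads (1.49 to 4.44 RPM) than the 6 others (0.388 to 1.19), but a single pseudogene held 56.3% of them, and the ratio of summed reads of 3.10 was 1.36 without it. More intron-containing RNA cannot be judged, since 17 intronic loci exceeded 11 exonic ones by 0.0835 (interval -1.09 to 1.22). A difference in library handling or an effect of the genotype stays open, untested.

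Reg1 and Gp2, both abundant in exocrine pancreas, could have come from the pancreas reads found in Ctrl 1. In the 2 Ctrl libraries with the elastase Cela2a under 1 FPKM, however, the lowest Reg1 value was 647 times and the lowest Gp2 value 189 times the highest WT value, which argues against carried-over pancreas as the cause. An effect of the Ctrl genotype, in which Cre and NICD come together, stays open, untested.

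The mast cell proteases Mcpt1, Mcpt2 and Mcpt4 rose together in Ctrl, which may reflect more mast cells in the scraped glands. The other 8 tested mast cell genes had a median log2 change of 0.73, with Il1rl1 higher (1.13, adjusted p = 0.0404) and Kit lower (-1.38, adjusted p = 0.0334), and Tpsb2 (0.85), Cpa3 (0.75), Cma1 (0.71) and Tpsab1 (adjusted p = 0.197) did not pass in limma. The explanation cannot be told apart from induction of the proteases, because members went both ways and the abundant ones, Tpsab1 at 21.3 ± 23.8 FPKM, varied widely. Mast cells lie in the mucosa and no sort removed them, and several of these genes, Kit among them, are also made by other gland or stromal cells.

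Splits of the 6 libraries of a comparison into 3 and 3 are 10 with the real one, too few for a share under 0.05. In Ctrl against WT the real split gave 1127 genes and the highest other 0, and of these splits 4 part all 3 pairs of same-numbered libraries, the real one included, while the others part 1 pair. In Arid1a_Het against Ctrl the real and the highest other gave 1 and 0 in limma. In Arid1a_Het against WT the real split gave 308 genes and the highest other 358. That split set Arid1a_Het 1, WT 1 and WT 3 against Arid1a_Het 2, Arid1a_Het 3 and WT 2. It points to a structure of the samples beside the genotype. The remaining 8 splits called 0.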
